A study of Mus musculus with 6 samples.

How the data were processed

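Total RNA of 6 mouse CD8+ T cell cultures, 3 in low IL-2/IL-7 and 3 in high IL-2, was made into libraries with an NEBNext Ultra kit and sequenced, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 with the genome build GRCm38 (mm10), without roles or parameters, and the annotation release and the strand setting were not given in the sources used here. 2 tables of the whole series were used.

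The first table held, per the file headers, a normalized signal for each gene and library. Every value above 0 was a whole multiple of the smallest step of its column within a tolerance of 0.001 (100% of values), so the deposited signal is read counts divided by 1 factor per library, and these read counts were recovered. The same deposited table gave the authors' log2 fold changes with standard errors, the Wald score, and p-values with adjusted p-values, which were used only for the comparison of calls at the end of the report. Its marks of changed genes, 4070 up and 4812 down, followed an unadjusted p below 0.05. The second table held the authors' deposited FPKM values. These were above 0 for 2115 to 2904 genes per library with 0 reads, and their ratio to reads per listed gene length ranged on the log2 scale from -0.72 to 1.28 (5th to 95th percentile), so they came from another estimate than the read counts. The tables held 54532 genes after 287 repeated entries with identical values were dropped, and 54495 gene IDs were found in GENCODE M21. Starts listed in the table equalled those of GENCODE M21 on GRCm38 for 1451 of 51055 genes, so the coordinates in the text are those of GENCODE M21 (GRCm38), matched by gene ID, and not those of the table.

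Recovered reads assigned to genes came to 15603919 to 17476523 per library. Libraries of the same group differed by more than counting noise (chi-square per degree of freedom of 8.60 to 47.6), so each counted as 1 replicate. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A group without reads of a gene was given a floor of 3 reads over its 3 libraries (over the other 2 where 1 was left out, a step added after seeing the data), and with 1 to 3 reads the ratio has an exact 95% interval. Read shares have 95% Wilson intervals.

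Because the first table holds normalized values, the main test was limma 3.58.1 (R 4.3.3) with a trend on log2(normalized count + 1), for the 17871 genes with a value of at least 1 in at least 3 libraries, with the group as the single term and Benjamini-Hochberg adjusted p below 0.05 as the threshold. Groups were taken from the sample titles. 35 gene lists were fixed before the data were examined, and the 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01. Lists were also counted gene by gene over the members that passed the filter, with p adjusted over all genes and over the list alone. Genes named in the text followed a rule also fixed before the data were examined. The rule took 10 genes in any case (1 of them is not reported here; the others were Il7r, Il2ra, Il2rb, Tcf7, Gzmb, Prf1, Ifng, Cd8a and Klrg1), and the 8 protein-coding genes per direction with the greatest log2 fold change among those called, without overlap of the groups and with a mean FPKM of at least 5 in the higher group, leaving out gene-model names. It also took up to 3 called members per list, by log2 fold change among those with a mean FPKM of at least 1 in the higher group, and for marker lists the 2 members with the highest mean FPKM. Other list members named as examples, Foxp3, Cd4, Ms4a1, Pax5, Igkc and the receptor V genes were chosen after their values were seen.

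The steps were tested on simulated counts drawn from the gene means and relative read totals of the 6 libraries with an assumed dispersion, with 200 changed genes among 17542 tested. The changed genes were drawn only from genes above a minimum mean count. Of 50 genes per fold, 40.0% were recovered at 1.5-fold, 82.0% at 2-fold, and 100% at 4-fold and at 8-fold. Far fewer genes were changed in the simulation than the 8459 called in the data, which makes the adjusted threshold stricter. These shares therefore do not give the sensitivity of the test in these data. The simulation gave 9 false calls (5.29% of calls), called the list that had been shifted and called 0 of 30 others. Its genes were drawn independently, whereas the correlation estimated within the real lists reached 0.588. The 0 of 30 therefore cannot show how often the set test makes false calls in these data. Read count tests on the recovered reads were run as alternatives with DESeq2 1.42.0, edgeR 4.0.16 and limma-voom, and other alternatives were the FPKM table, filters, pseudocounts, scalings, the replicate number as a block, each replicate left out, an estimated correlation and fry. Scaling to library totals, TMM scaling, totals without ribosomal protein genes, a pseudocount of 0.1 on normalized counts, edgeR with TMM, counts of called list members with a library left out, leaving out both libraries numbered 1 and a term for these libraries were added after seeing the data. Python 3.11.15 with SciPy 1.17.1 was used for intervals and matplotlib 3.10.9 for figures.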

Results

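RNA was sequenced from 6 cultures of mouse CD8+ T cells, 3 in each of 2 cytokine conditions. Naive CD8+ T cells of C57BL/6 spleens were stimulated for 48 h with beads that carry antibodies to CD3 and CD28, and were then kept for 8 days at 100000 cells per ml. One group, low IL-2/IL-7, received 4 ng/ml IL-2 with 10 ng/ml IL-7, and the other group, high IL-2, received 100 ng/ml IL-2 alone. IL-2 drives the expansion of activated T cells, and IL-7 is a survival factor of naive and memory T cells. The groups differed in both cytokines, so the comparison does not separate the IL-2 dose from IL-7. The sample titles call the 3 libraries of a group biological replicates without saying whether each came from a separate mouse, so p-values measure the spread between these cultures. The series title speaks of day 8 of an LCMV infection, whereas the culture protocol names no infection, and the protocol was followed here.

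The libraries held 15603919 to 17476523 reads assigned to genes, and 13030 to 13452 genes had at least 10 reads in a library. The first principal component held 73.1% of the variance and separated the groups. The correlation of log2 values across genes was 0.969 to 0.983 within groups and 0.894 to 0.909 between groups. Ribosomal protein genes took 12.4% ± 0.569 of the reads in low IL-2/IL-7 and 8.85% ± 0.247 in high IL-2 (SD, n = 3), and mitochondrial transcripts took 2.88% ± 0.438 and 2.21% ± 0.399.

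The question of the comparison was how the 2 expansion conditions differ in gene expression. CD8+ T cells expanded in low IL-2/IL-7 had more mRNA for receptors and transcription factors of naive and memory T cells, such as Il7r and Tcf7. Cells expanded in high IL-2 had more mRNA for granzymes, glycolysis, lipid synthesis and cell division. Il7r, the receptor chain for IL-7, stood at 3645 ± 149 normalized read counts in low IL-2/IL-7 and 92.5 ± 48.6 in high IL-2 (SD, n = 3 each), a log2 difference of 5.41 ± 0.29 (SE; limma, adjusted p = 9.88e-07). Gzmb, a granzyme that kills target cells, stood at 3676 ± 1175 against 59233 ± 10806 and was lower in low IL-2/IL-7 by a log2 value of -4.04 ± 0.21 (adjusted p = 8.36e-07). Ube2c and Bub1, which act in mitosis, had 39.8 ± 10.2 and 22.3 ± 12.5 normalized counts in low IL-2/IL-7 and 3844 ± 623 and 2028 ± 649 in high IL-2.

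Of 17871 genes tested, 8459 changed at an adjusted p below 0.05, with 3856 higher in low IL-2/IL-7 and 4603 higher in high IL-2. At least 2-fold changes were estimated for 4947 of them, 1947 higher in low IL-2/IL-7 and 3000 higher in high IL-2. A test against a fold of 2 (treat in limma) called 2114 genes. The fit on log2(FPKM + 1) values gave 2426 at least 2-fold genes. It tested only the 12163 genes with an FPKM of at least 1 in at least 3 libraries, so 2426 and 4947 are not counts over the same genes. Values of the 2 groups did not overlap for 57.0% of the tested genes, where chance gives 10%. Log2 fold changes are low IL-2/IL-7 minus high IL-2 on the scale of normalized count + 1, which understates the change of genes with few reads. A gene said to fall in low IL-2/IL-7 was lower there than in high IL-2. No sample from before the culture was included, so changes over time were not measured.

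**Figure D1:**
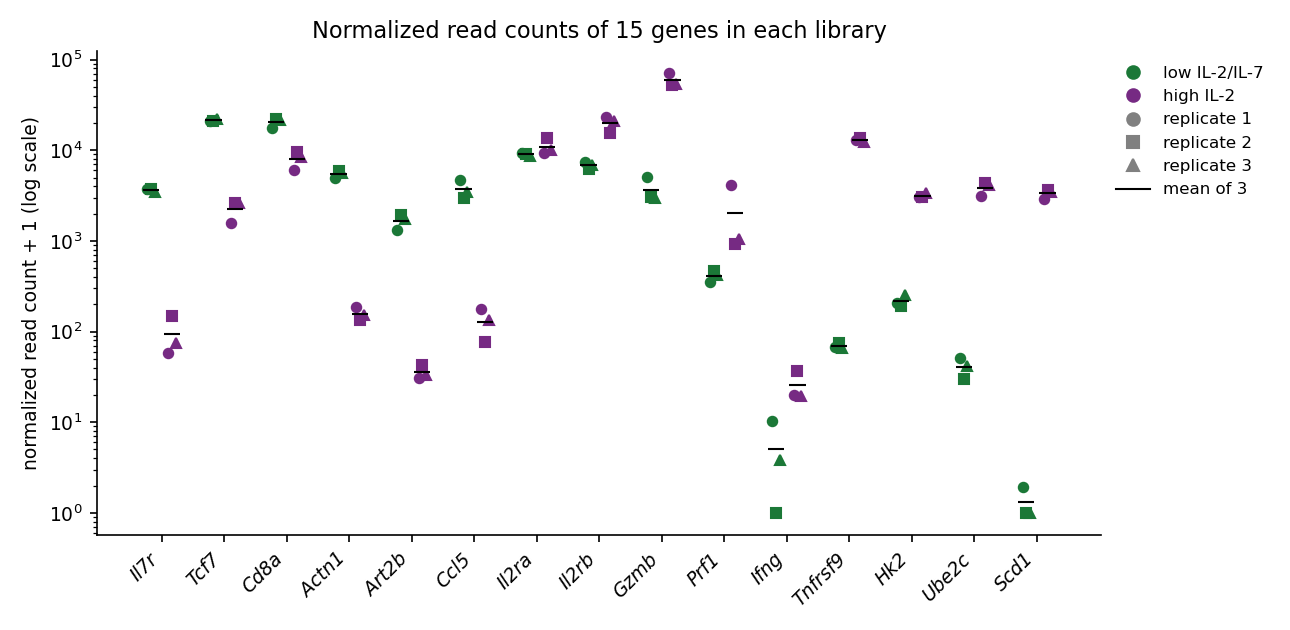
Normalized read counts + 1 (log axis) of 15 genes in the 3 low IL-2/IL-7 libraries (green) and the 3 high IL-2 libraries (purple), with the mean of each group as a bar and a marker shape per replicate number. Il7r lay between 3474 and 3750 in low IL-2/IL-7 and between 56.3 and 147.8 in high IL-2, whereas the Il2ra values of the groups overlapped.

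Among the genes with the greatest difference toward low IL-2/IL-7 were Syt6, a synaptotagmin (log2 difference 6.66 ± 0.44), the tetraspanin Tspan32 (6.50 ± 0.39), Pgpep1l (6.31 ± 0.39), the ADP-ribosyltransferase Art2b (5.55 ± 0.20), Actn1, which encodes an actin-binding alpha-actinin (5.13 ± 0.14), the VIP receptor Vipr1 (4.93 ± 0.23) and the chemokine Ccl5 (4.91 ± 0.28). Their adjusted p-values lay between 6.99e-08 and 3.46e-06, and the Syt6 difference was 6.05 without high IL-2 replicate 3. Among the genes with the greatest difference toward high IL-2, Scd1, the stearoyl-CoA desaturase on chromosome 19 (GRCm38, 44394455 to 44407879), had 1 read over the low IL-2/IL-7 libraries and 9787 over the high IL-2 libraries. That is a ratio of 10586 with an exact 95% counting interval of 1899.6 to 418180. Fads2, a fatty acid desaturase, had 3 and 6384 reads, a ratio of 2302 (787 to 11165), and the transglutaminase Tgm2 had 3 and 12619, a ratio of 4549.9 (1556.5 to 22066). Without low IL-2/IL-7 replicate 1, which held all low IL-2/IL-7 reads of Scd1 and Fads2, these genes were at least 2333-fold and 1522-fold higher in high IL-2, and the log2 difference of Fads2 was -11.10 in place of -10.45. The Tgm2 ratio was 9212.5 without low IL-2/IL-7 replicate 2, and without replicate 3, which held no reads of these genes, the ratios of Scd1, Fads2 and Tgm2 were 7029, 1528 and 3021. Gzmd, Gzme and Gzmg had 0 reads in every low IL-2/IL-7 library and were at least 2081-fold, 959.8-fold and 842-fold higher in high IL-2, against a floor of 3 reads over the group. Without high IL-2 replicate 1, which held most of their reads, these bounds were 811-fold, 280-fold and 300-fold. The cytokine Il24 had 0 reads in low IL-2/IL-7 and was at least 389.8-fold higher in high IL-2. With a low IL-2/IL-7 library left out, all such bounds fell through the floor alone, that of Gzmd to 1376-fold at the lowest. H2-Ab1, a class II histocompatibility chain, had 2.22 ± 1.44 normalized counts in low IL-2/IL-7 and 988 ± 113 in high IL-2. Gzmd, Gzme, Gzmf and Gzmg are near-identical copies on chromosome 14 whose reads can be shared, so their separate values are uncertain.

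Of 25 naive and memory T cell genes, 20 were higher in low IL-2/IL-7, 1 was higher in high IL-2 and 4 were not called; adjusted over the list alone the counts were 22 and 1. Tcf7, the transcription factor TCF1 on chromosome 11 (52252371 to 52283014), was higher by 3.27 ± 0.18, with 21473 ± 580 against 2275 ± 589 normalized counts. Il6ra, the IL-6 receptor chain, was higher by 4.13 ± 0.34, and Klf2 and S1pr1, which keep T cells in circulation, were higher by 4.06 and 3.82. Eomes, a T-box factor of effector and memory cells, was the member that fell in low IL-2/IL-7, by 2.46 on the log2 scale. The list was called higher as a set (camera, adjusted p = 2.41e-10; adjusted p = 0.162 with an estimated correlation). Of 18 T cell receptor and CD8 lineage genes, 8 were higher in low IL-2/IL-7, among them Cd8a (1.35 ± 0.18), Cd8b1 (1.71 ± 0.09) and Cd5 (1.69 ± 0.37). Runx3, which represses Cd4, was higher in high IL-2, 9 members were not called, and adjusted over the list alone the counts were the same. Without low IL-2/IL-7 replicate 3, 5 in place of 8 were higher in low IL-2/IL-7. This list was called higher in low IL-2/IL-7 (adjusted p = 0.0261; adjusted p = 0.249 with an estimated correlation), but not without high IL-2 replicate 2 (adjusted p = 0.0527), with a mean FPKM of at least 5 (0.0516) or with log2(FPKM + 1) or log2(FPKM + 0.1) values (0.0593 and 0.0565). Of 28 autophagy and lysosome genes, 15 were higher in low IL-2/IL-7, 3 were higher in high IL-2 and 10 were not called (16 and 3 adjusted over the list alone). Ctsl and Ctss, lysosomal cathepsins, were higher by 1.91 and 1.49, and Atg2a by 1.32 (set adjusted p = 0.000573; adjusted p = 0.162 with an estimated correlation).

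Of 18 cytotoxic granule and death ligand genes, 13 were higher in high IL-2, 2 were higher in low IL-2/IL-7 and 3 were not called (13 and 3 adjusted over the list alone). Besides Gzmb, the pore-forming protein Prf1 fell by 1.94 on the log2 scale in low IL-2/IL-7 (SE 0.47, adjusted p = 0.00807), and Fasl, the Fas ligand, by 4.32. Serpinb9, which inhibits granzyme B, fell by 3.57. Tnfsf10 (TRAIL) and Lamp1 were higher in low IL-2/IL-7, by 0.56 and 0.48. Only 1 member was higher there with any 1 of the 3 low IL-2/IL-7 libraries left out or without high IL-2 replicate 3. The list median was -3.23, the same with the 4 granzymes without reads at their bounds (set adjusted p = 9.17e-05; adjusted p = 0.32 with an estimated correlation). High IL-2 replicate 1 stood apart in this group: it had 4514 normalized counts of Gzmd and 4124 of Prf1, while the other 2 high IL-2 libraries had 753.6 and 792 of Gzmd and 917 and 1044 of Prf1. Without high IL-2 replicate 1, Prf1 was lower in low IL-2/IL-7 by a log2 value of -1.25. The list median was -1.47 without high IL-2 replicate 1, -2.29 without replicate 2 and -2.10 without replicate 3. Each of these fits tested 14 in place of 18 members. Gzmd, Gzme, Gzmf and Gzmg, without reads in low IL-2/IL-7, fail the filter of 3 libraries once a high IL-2 library is left out. These medians therefore do not show the effect of a replicate alone. Without the libraries numbered 1, 9 of 14 tested members were higher in high IL-2 and 2 were higher in low IL-2/IL-7, with a median of -1.35 and a Prf1 difference of -1.15.

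Of 21 genes induced by IL-2 through STAT5, 12 were higher in high IL-2, 4 were higher in low IL-2/IL-7 and 5 were not called, with the same counts adjusted over the list alone. Tnfrsf9 (4-1BB), a costimulatory receptor, fell by 7.55 on the log2 scale in low IL-2/IL-7 (SE 0.11, adjusted p = 1.31e-09), Lif by 8.05, the cell cycle inhibitor Cdkn1a by 4.60 and Il2rb, the shared IL-2 and IL-15 receptor chain, by 1.52. Il2ra, the high-affinity IL-2 receptor chain, did not pass the test, with 8989 ± 324 and 10976 ± 2288 normalized counts (adjusted p = 0.157). The Lif difference was -8.66 without low IL-2/IL-7 replicate 1 and -7.44 without replicate 2. Socs3, Ltb and Pim1 were among the members higher in low IL-2/IL-7, by 1.72, 1.33 and 0.78 (set adjusted p = 0.00908 toward high IL-2; adjusted p = 0.389 with an estimated correlation). Without low IL-2/IL-7 replicate 3, only 2 members were higher there. Of 14 effector differentiation genes, 7 were higher in high IL-2, including the transcription factors Nfil3, Bhlhe40 and Irf4, lower by log2 values of -5.56, -3.15 and -2.97 in low IL-2/IL-7. Runx1, Ikzf2 and Ikzf3 were higher in low IL-2/IL-7, 4 members were not called, the counts adjusted over the list alone were the same, and the set was not called (adjusted p = 0.182; 0.030 with a mean FPKM of at least 5). Klrg1, a marker of terminal effector cells, had 8 reads over the low IL-2/IL-7 libraries and 1 over the high IL-2 libraries and was not called (adjusted p = 0.0922).

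Of 16 inhibitory receptor and exhaustion genes, 9 were higher in high IL-2, 1 was higher in low IL-2/IL-7 and 6 were not called, with the same counts adjusted over the list alone. Havcr2 (TIM-3) fell by 6.52 in low IL-2/IL-7, Cd244a by 4.32 and the ectonucleotidase Entpd1 (CD39) by 3.72, while the attenuator Btla was higher there by 2.82 (set adjusted p = 0.00876; adjusted p = 0.313 with an estimated correlation). Without high IL-2 replicate 2, 2 members were higher in low IL-2/IL-7. The set was not called with log2(FPKM + 1) or log2(FPKM + 0.1) values (adjusted p = 0.102 and 0.0946) or with a mean FPKM of at least 5 (0.245). Havcr2 also stood at 545 normalized counts in high IL-2 replicate 1 and at 93.8 and 126.5 in the other high IL-2 libraries, and its log2 difference was -5.75 without replicate 1 and -5.24 without both libraries numbered 1. Cd244a overlaps Ly9, and no source states that the libraries or the counting kept the strand, so part of its reads is uncertain. The same holds for Tgm2, Tnfrsf9, Cxcr5, Itgae, Gls2, Pcx and Trdc, which also overlap other annotated genes. The cytokine list held 18 genes, of which 9 passed the filter. Of these 9, 7 were higher in high IL-2, 1 (Il4) was higher in low IL-2/IL-7 and 1 was not called, also when adjusted over the list alone. None was higher in low IL-2/IL-7 without replicate 3 of either group. The immune-suppressive cytokine Il10 had 0 reads in low IL-2/IL-7 and was at least 68.1-fold higher in high IL-2, with 157 normalized counts in replicate 1 and 20.2 and 21.3 in the others and a bound of 21.8-fold without replicate 1, and the growth factor Csf2 fell by 4.24 in low IL-2/IL-7. Ifng stood at 4.06 ± 4.80 and 24.5 ± 10.0 normalized counts (log2 difference -2.84 ± 0.79, adjusted p = 0.015; adjusted p = 0.0597 with a pseudocount of 0.1), and with a low IL-2/IL-7 library left out the difference ranged from -3.64 to -1.95 (-3.78 without both libraries numbered 1). That of Csf2 was -3.49 without low IL-2/IL-7 replicate 3. The cytokine list was called toward high IL-2 (adjusted p = 0.0142, and 0.172 with an estimated correlation), but not without high IL-2 replicate 1, 2 or 3 (adjusted p = 0.0942 to 0.108) or without both libraries numbered 1 (0.0633). Each of these fits tested 7 in place of 9 members. Il10 and Il24, without reads in low IL-2/IL-7, cannot pass the filter of 3 libraries once a high IL-2 library is left out. The lost call therefore does not by itself show dependence on a replicate.

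Of 16 chemokine and receptor genes, 5 were higher in low IL-2/IL-7, including Ccl5, Cxcr5 and Ccr7, and 6 were higher in high IL-2, including Ccr4 and Ccr2 (same counts adjusted over the list alone; set adjusted p = 0.989). Another 5 were not called, and the median of all 16 was -0.15 while their mean was 0.16 and the test pointed to low IL-2/IL-7. The log2 difference of Cxcr5, 4.23 ± 0.89, was 5.25 without high IL-2 replicate 1 and 3.31 without high IL-2 replicate 3. Of 16 adhesion and tissue residency genes, 9 were higher in high IL-2, led by the cadherin Cdh1 and the residency marker Cd69, which fell by 6.45 and 3.12 in low IL-2/IL-7. Another 4 were higher in low IL-2/IL-7, among them the integrin chain Itgae (2.96 ± 0.23), with the same counts adjusted over the list alone and no call as a set (adjusted p = 0.0794; 0.0272 without high IL-2 replicate 3 and 0.048 without a filter). Of 20 natural killer receptor genes, 14 passed the filter. Of these 14, 7 were higher in high IL-2 and 1, Cd7 (4.13 ± 0.24), was higher in low IL-2/IL-7. The counts adjusted over the list alone were 8 and 2, and the set was not called (camera, adjusted p = 0.327). In low IL-2/IL-7, 2 were higher without low IL-2/IL-7 replicate 1 or high IL-2 replicate 2. Klrb1c and the signalling adaptor Fcer1g fell by 4.49 and 2.93 in low IL-2/IL-7, and the Klrb1c difference was -3.44 without low IL-2/IL-7 replicate 1 and -5.13 without replicate 3. Without both libraries numbered 1, the differences of Klrb1c and Fcer1g were -2.88 and -2.20.

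**Figure D2:**
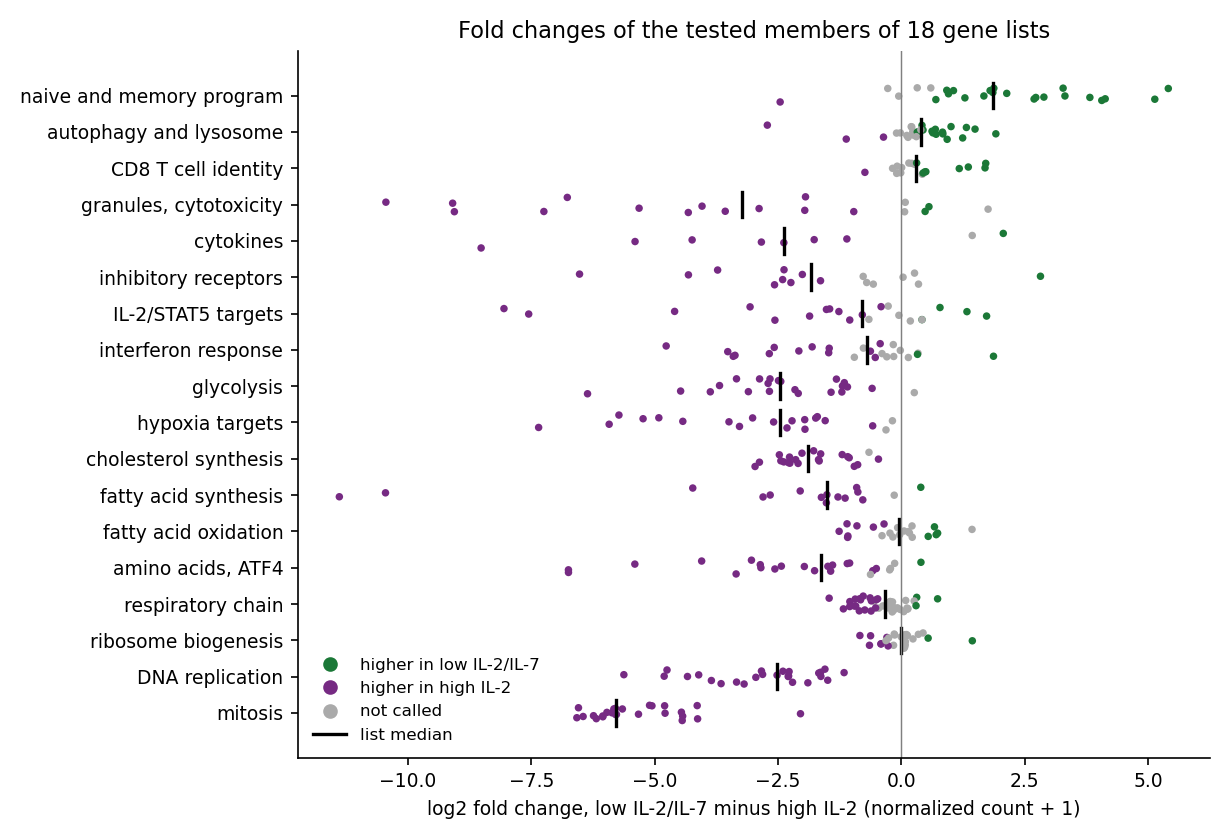
Log2 fold changes (low IL-2/IL-7 minus high IL-2, normalized count + 1) of the tested members of 18 gene lists, 1 point per gene, coloured by the limma call, with the list median as a bar. Members of the mitosis list had a median of -5.77 and those of the naive and memory list a median of 1.85.

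Genes of cell division were higher in high IL-2 throughout both lists. All 25 DNA replication genes and all 25 mitosis genes were higher in high IL-2, also when adjusted over the list alone. Cdc6, which licenses replication origins, fell by 5.62 in low IL-2/IL-7, the ribonucleotide reductase subunit Rrm2 by 4.81, the ubiquitin-conjugating enzyme Ube2c by 6.58 and the checkpoint kinase Bub1 by 6.54 (by 7.15 without both libraries numbered 1). The set adjusted p-values were 6.74e-18 for replication and 1.43e-21 for mitosis (adjusted p = 0.106 and 0.162 with an estimated correlation). Of 25 ribosome biogenesis genes, 7 were higher in high IL-2, including the nucleolar proteins Ncl and Npm1, which fell by 0.84 and 0.65 in low IL-2/IL-7. Rrp12 (1.44 ± 0.16) and Gnl3 were higher in low IL-2/IL-7 and 16 were not called (5 and 2 adjusted over the list alone; set adjusted p = 0.678). Without low IL-2/IL-7 replicate 2, only 3 were higher in high IL-2.

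Of 22 glycolysis genes, 21 were higher in high IL-2 and none was higher in low IL-2/IL-7, also when adjusted over the list alone. The lactate exporter Slc16a3 fell by 6.36 in low IL-2/IL-7, Aldoc by 4.47 and the hexokinase Hk2 by 3.87, while the pyruvate dehydrogenase kinase Pdk1 stood at 6782 and 5725 normalized counts and was not called. Of 20 hypoxia-inducible factor targets, 18 were higher in high IL-2 and 2 were not called (19 adjusted over the list alone), with Ak4, Vegfa and the collagen hydroxylase P4ha2 lower by log2 values of -7.35, -5.92 and -5.72 in low IL-2/IL-7. Cholesterol synthesis genes were higher in high IL-2 in 21 of 22 cases (22 adjusted over the list alone), including Idi1 and Hmgcs1, which fell by 2.97 and 2.88 in low IL-2/IL-7. Of 16 fatty acid synthesis genes, 14 were higher in high IL-2 and Elovl5 was higher in low IL-2/IL-7 by 0.39, with the same counts adjusted over the list alone. Its call was not kept when any 1 library other than high IL-2 replicate 2 was left out. Beyond Scd1 and Fads2, Scd2 fell by 4.23 in low IL-2/IL-7. The set adjusted p-values were 8.39e-14 for glycolysis, 2.23e-11 for hypoxia targets, 3.91e-12 for cholesterol synthesis and 3.07e-07 for fatty acid synthesis. These became adjusted p = 0.162, 0.131, 0.106 and 0.131 with an estimated correlation. Of 16 gluconeogenesis, glycogen and pentose phosphate genes, 13 were higher in high IL-2 and 3 were not called, also when adjusted over the list alone. Pygl, the glycogen phosphorylase, fell by 7.51 in low IL-2/IL-7 and the pyruvate carboxylase Pcx by 4.18 (set adjusted p = 5.44e-06; adjusted p = 0.162 with an estimated correlation).

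Of 24 amino acid transport and ATF4 target genes, 19 were higher in high IL-2, Slc7a6 was higher in low IL-2/IL-7 and 4 were not called (20 and 1 adjusted over the list alone). The transporter Slc1a4 fell by 6.75 in low IL-2/IL-7 and the asparagine synthetase Asns by 3.35, and Chac1, with 0 reads in low IL-2/IL-7, was at least 115-fold higher in high IL-2 (set adjusted p = 1.73e-08; adjusted p = 0.106 with an estimated correlation). Of 16 urea cycle and glutamine genes, 10 were higher in high IL-2, led by the alanine transaminase Gpt2 and the glutaminase Gls2, which fell by 5.88 and 5.04 in low IL-2/IL-7. Arg1 and Glul were higher in low IL-2/IL-7, with the same counts adjusted over the list alone. Without both libraries numbered 1, 6 in place of 10 were higher in high IL-2. No member was higher in low IL-2/IL-7 without high IL-2 replicate 1 or low IL-2/IL-7 replicate 3. Only 1 was without low IL-2/IL-7 replicate 1 or 2 (set adjusted p = 0.0221; adjusted p = 0.249 with an estimated correlation). Of 22 fatty acid oxidation genes, 7 were higher in high IL-2, 4 were higher in low IL-2/IL-7 and 11 were not called, also when adjusted over the list alone, with Acadl lower in low IL-2/IL-7 by a log2 value of -1.26 and a median of -0.06 (set adjusted p = 0.678). Cpt1a, which admits fatty acids to mitochondria, was not called, with 889.9 and 812 normalized counts. Of 21 citric acid cycle genes, 11 were higher in high IL-2, including the fumarase Fh1, which fell by 1.00 in low IL-2/IL-7, and 10 were not called, also when adjusted over the list alone. The set adjusted p was 0.0208 (adjusted p = 0.249 with an estimated correlation), and the set was not called with log2(FPKM + 1) or log2(FPKM + 0.1) values (0.0593 and 0.0565) or with totals without ribosomal protein genes (0.0665). Without high IL-2 replicate 2, 1 member was higher in low IL-2/IL-7. Without both libraries numbered 1, 7 in place of 11 were higher in high IL-2. Of 42 nuclear respiratory chain genes, 18 were higher in high IL-2, such as Cycs (cytochrome c), which fell by 1.46 in low IL-2/IL-7, and 3 were higher in low IL-2/IL-7 (21 and 3 adjusted over the list alone; set adjusted p = 0.00394; adjusted p = 0.389 with an estimated correlation). Only 1 was higher in low IL-2/IL-7 with any 1 of the 3 low IL-2/IL-7 libraries left out or without high IL-2 replicate 1. Of 13 mitochondrially encoded genes, 5 were higher in low IL-2/IL-7, 1 was higher in high IL-2 and 7 were not called, with the same counts adjusted over the list alone (set adjusted p = 0.168; 0.0294 without low IL-2/IL-7 replicate 1 and 0.045 without high IL-2 replicate 2). With log2(FPKM + 1) and log2(FPKM + 0.1) values this set was called higher in low IL-2/IL-7 (adjusted p = 0.0207 and 0.022), with a median of 0.55 in both in place of 0.29. The member higher in high IL-2, mt-Nd3, was not called with these values (adjusted p = 0.817 in both), without low IL-2/IL-7 replicate 1 or high IL-2 replicate 2 or 3 (0.0731 to 0.104) or with totals without ribosomal protein genes (0.0509). Without low IL-2/IL-7 replicate 2 or 3 or high IL-2 replicate 3, 3 in place of 5 were higher in low IL-2/IL-7. Over all libraries mt-Nd4 and mt-Nd2 were higher in low IL-2/IL-7 by 0.76 and 0.75.

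Of 24 interferon-stimulated genes, 13 were higher in high IL-2, with Ifitm3 lower by a log2 value of -4.77, Oasl2 by -3.52 and Isg20 by -2.68 in low IL-2/IL-7. Ifit3 and Irf9 were higher in low IL-2/IL-7 and 9 were not called, also when adjusted over the list alone (set adjusted p = 0.00705; adjusted p = 0.471 with an estimated correlation). Only 1 was higher in low IL-2/IL-7 with any 1 of the 3 low IL-2/IL-7 libraries left out or without high IL-2 replicate 3. Of 18 BCL2 family and death genes, 6 were higher in high IL-2, including Bcl2l1 (BCL-XL), which fell by 1.45 in low IL-2/IL-7, and 4 were higher in low IL-2/IL-7, among them Mcl1 (1.01). The other 8 were not called, the counts adjusted over the list alone were the same and the set adjusted p was 0.597. Of 18 immediate-early and heat shock genes, which also respond to handling, 5 were higher in each group and 8 were not called, also when adjusted over the list alone (set adjusted p = 0.678). The median of this list was 0.16 and its mean -0.17, and the test pointed to low IL-2/IL-7. Zfp36 was higher in low IL-2/IL-7 by 1.92, and Egr1 fell by 2.49 there, with 3272 normalized counts in high IL-2 replicate 1 and 454 and 786 in the other high IL-2 libraries. Its log2 difference was -1.68 without replicate 1 and -3.10 without replicate 2 of high IL-2.

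Markers of other cell types were counted among the genes that passed the filter. These were 7 of 14 B cell, 7 of 11 dendritic cell and 4 of 5 CD4 and regulatory T cell markers. Of the myeloid markers 3 of 18 passed, and 4 of 13 in each of the erythroid and platelet and the stromal and endothelial lists. The B cell list had 4 of 7 tested members higher in low IL-2/IL-7 (Ighm, Ighd, Cd79a and Cd79b) and none higher in high IL-2, also when adjusted over the list alone (set adjusted p = 0.044; adjusted p = 0.32 with an estimated correlation). Ighm, the IgM heavy chain constant gene, had 13610 ± 738 normalized counts in low IL-2/IL-7 and 2443 ± 1286 in high IL-2, whereas Ms4a1 and Pax5 had 0 reads in all 6 libraries and Igkc 2 reads in total in low IL-2/IL-7. The set was not called without high IL-2 replicate 2 (adjusted p = 0.0504), with library totals (0.0541), with a pseudocount of 0.1 (0.0578) or with totals without ribosomal protein genes (0.0666). Among 7 dendritic cell markers, 3 were higher in high IL-2, none in low IL-2/IL-7 and 4 were not called, also when adjusted over the list alone (set adjusted p = 0.0972; 0.049 without the libraries numbered 1). They were H2-Ab1, Xcr1 and H2-Eb1, the last at 1.90 and 6.89 normalized counts, while Cd74 stood at 12.7 and 23.6 and was not called. Of 4 tested CD4 and regulatory T cell markers, Foxp3 and Cd40lg were higher in low IL-2/IL-7 and Zbtb7b and Ikzf4 in high IL-2, also when adjusted over the list alone. The Ikzf4 call was lost with log2(FPKM + 1) and log2(FPKM + 0.1) values (adjusted p = 0.0777 and 0.0812). Foxp3 stood at 177 ± 58.3 and 4.71 ± 2.63 normalized counts, while Cd4 had 0 reads in low IL-2/IL-7 and 1 in high IL-2. Of 3 tested myeloid markers, Ly6g and Cd68 were higher in high IL-2, Cd68 at 105 and 170 normalized counts, and its call was lost without low IL-2/IL-7 replicate 2 (adjusted p = 0.0648) or without both libraries numbered 1 (0.0647). Of 4 erythroid and platelet markers, Itga2b was higher in low IL-2/IL-7 and Hba-a1 in high IL-2, and the Itga2b call was lost without low IL-2/IL-7 replicate 1 or 3, high IL-2 replicate 2 or both libraries numbered 1 (adjusted p = 0.051 to 0.0977). Of 4 stromal and endothelial markers, Pecam1 and Cdh5 were higher in low IL-2/IL-7 and Kdr in high IL-2, with Pecam1 at 2608 ± 279 and 654 ± 153 normalized counts. The counts of these 3 lists were the same adjusted over the list alone, and with too few tested members none of the CD4, myeloid, erythroid and stromal lists was tested as a set. With a library left out, fewer marker genes passed the filter or the test. Only 1 CD4 and regulatory T cell marker was higher in low IL-2/IL-7 when any 1 library of that group was left out. When any 1 high IL-2 library was left out, 1 myeloid and 0 erythroid and platelet markers were higher in high IL-2. Only 1 stromal marker was higher in low IL-2/IL-7 when any 1 of the 6 libraries was left out. Ly6g and Hba-a1 had 0 reads in low IL-2/IL-7, and Cd40lg and Cdh5 had 0 in high IL-2. Such genes cannot pass the filter of 3 libraries once a library of the group that holds their reads is left out. Losses of this kind do not by themselves show dependence on a replicate. With a high IL-2 library left out, Ly6g and Hba-a1 stayed at least 12.8-fold and 5.86-fold higher in high IL-2. With genes without reads at their bounds, the median of the CD4 and regulatory T cell markers went from 1.20 to 1.14 and the medians of all other lists stayed as they were.

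The libraries numbered 1 in both groups stood apart in T cell receptor genes. Trbv13-3 held 49.0% (95% Wilson interval 45.8 to 52.2) and 41.7% (37.1 to 46.5) of the reads of beta chain V genes in these libraries, and 2.90% to 4.24% in the other 4. Beta chain V genes together had 920 and 422 reads in these libraries and 3300 to 5140 in the other 4. Trbv13-3 itself had 451 and 176 reads against 97 to 160. Its share thus rose largely because reads of other beta chain V genes were fewer. Trav14-1 held 65.9% (63.4 to 68.3) and 66.3% (63.3 to 69.2) of the reads of alpha chain V genes, and 2.85% to 3.32% in the other 4. Trdc, the delta chain constant gene, had 9716 and 5111 normalized counts in the libraries numbered 1 and 166 to 1263 in the others, and over all 6 libraries its log2 difference of 1.95 was not called with the group as the single term (adjusted p = 0.218). It was called higher in low IL-2/IL-7 over all 6 with the replicate number as a block (adjusted p = 0.000173) or with a term for the libraries numbered 1 (0.000685). Without high IL-2 replicate 1, Trdc was higher in low IL-2/IL-7 by 3.45 (adjusted p = 0.00796), and without both libraries numbered 1 by 2.45 (0.000227), while without low IL-2/IL-7 replicate 1 or high IL-2 replicate 3 the difference was 0.95 or 0.99 and not called. Of 7 gamma-delta T cell markers, Tcrg-C4 was higher in low IL-2/IL-7 and Tcrg-C1 in high IL-2 (same counts adjusted over the list alone; set adjusted p = 0.678). Without high IL-2 replicate 1, 2 were higher in low IL-2/IL-7, and without low IL-2/IL-7 replicate 1, 2 were higher in high IL-2. The Tcrg-C1 call was lost without low IL-2/IL-7 replicate 2, low IL-2/IL-7 replicate 3 or high IL-2 replicate 1 (adjusted p = 0.0759 to 0.0865), with log2(FPKM + 1) and log2(FPKM + 0.1) values (0.0591 and 0.0614) and with DESeq2 (0.0608). Within the libraries numbered 2 and 3, 6003 genes changed, 2817 higher in low IL-2/IL-7 and 3186 higher in high IL-2, and 5851 of these were also called, in the same direction, over all 6 libraries. The pair numbered 1, 1 library per group and so without a test, had the same direction for 5932 of the 6003 genes (98.8%).

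**Figure D3:**
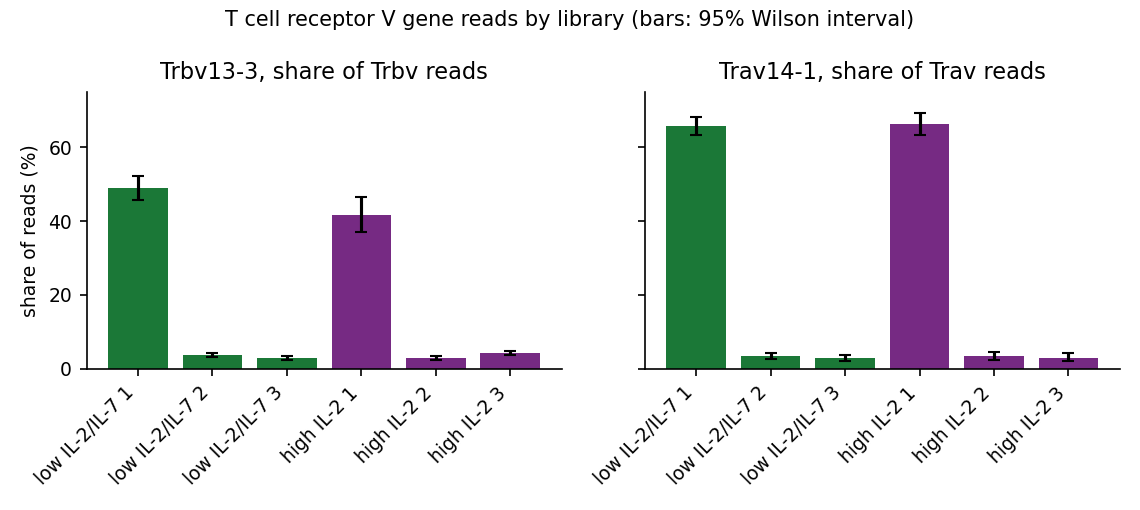
Share of the reads of beta chain V genes that Trbv13-3 took and of alpha chain V genes that Trav14-1 took, in percent, in each library, with 95% Wilson intervals. The shares lay between 41.7% and 66.3% in the number 1 library of each group and between 2.85% and 4.24% in the other 4. Reads of all beta chain V genes were fewer in the number 1 libraries (920 and 422) than in the other 4 (3300 to 5140).

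The gene test was limma with a trend on log2(normalized count + 1) and Benjamini-Hochberg adjustment over all tested genes. The set test was camera with a preset correlation of 0.01 between genes. It called 20 of 31 lists, 4 higher in low IL-2/IL-7 and 16 higher in high IL-2. Other splits of the 6 libraries into 3 and 3, made after the data had been seen, still gave 11 to 17 called lists. These splits mix the groups unevenly and keep part of their difference, so they cannot give the share of false list calls. A set call at the preset correlation is therefore weak evidence by itself. With a correlation estimated for each list camera called 0 of the 31 lists (9 at an unadjusted p below 0.05), and fry, which does not compare a list with other genes, called 24. The authors' deposited table gave 3538 genes higher in low IL-2/IL-7 and 4300 higher in high IL-2 at an adjusted p below 0.05, and 7678 genes were called in both tables in the same direction and 0 in opposite directions.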

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

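The scalings to library totals, by TMM and to totals without ribosomal protein genes, the pseudocount of 0.1 on normalized counts, edgeR with TMM, and the fits without the libraries numbered 1 or with a term for them were chosen after the data had been seen. So were the counts of called list members and the floors with a library left out. The other alternatives were fixed before the data were examined. A filter at a mean FPKM of 5, which tests fewer genes, gave 4921 changed genes (2343 higher in low IL-2/IL-7, 2578 higher in high IL-2), 1967 of them at least 2-fold (790 and 1177), and 2 lists higher in low IL-2/IL-7 in place of 4. The log2(FPKM + 1) values gave 2426 genes at least 2-fold (910 and 1516), and log2(FPKM + 0.1) gave 3119 in all and 1807 higher in high IL-2. Both fits had a filter on FPKM and tested 12163 genes in place of 17871. How much of the lower counts this explains was not tested. Rpl13a, Cox17 and Tomm6 were called in opposite directions by counts and by log2(FPKM + 1). The test against a fold of 2 called 2114 genes (576 and 1538), since it asks for more than an estimate of 2-fold. With an estimated correlation camera called 0 lists, 0 in each direction (9 at an unadjusted p below 0.05).

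Leaving out each replicate in turn gave 6728 to 8356 changed genes, with 2869 to 4054 higher in low IL-2/IL-7 and 3655 to 4302 higher in high IL-2. It gave 4091 to 4576 at least 2-fold genes (1553 to 1859 and 2253 to 2872) and 18 to 21 called lists (3 to 5 and 15 to 16). The fit with the replicate block gave 8939 changed genes (4147 and 4792), 5041 of them at least 2-fold, and 20 lists. Deviations of libraries with the same number correlated at 0.429, 0.413 and 0.042 across genes. For numbers 1 and 2 this was above every pair with different numbers, and their crossed pairs had -0.434 and -0.354. Low IL-2/IL-7 replicate 3 correlated best with high IL-2 replicate 2 (0.177). Deviations sum to 0 within a group, so the value of replicate 3 is not separate evidence. The labels do not say that a number marks a shared source, so the main test did not pair the libraries. A pairing is not excluded, and the block fit allows for it. DESeq2 on recovered reads called 7838 genes, edgeR with TMM 7672 and limma-voom 7725. Totals without ribosomal protein genes moved the median fold change by 0.10 on the log2 scale and gave 51.9% of calls higher in low IL-2/IL-7, against 45.6% as deposited.

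The medians of 4 lists without a call changed sign in some alternatives. The chemokine list, at -0.15, went to 0.18 without a filter and ranged from -1.004 to 0.20 with each replicate left out, with 0.14, 0.20 and 0.14 without low IL-2/IL-7 replicate 2 or high IL-2 replicate 2 or 3. Ribosome biogenesis, at -0.01, ranged from -0.074 to 0.043 with each replicate left out, the latter without low IL-2/IL-7 replicate 1, and went to 0.00196 and 0.00208 with FPKM values, 0.039 with library totals, 0.00744 with TMM, 0.097 without ribosomal protein genes and 0.00443 without the libraries numbered 1. Fatty acid oxidation went to 0.046 with totals without ribosomal protein genes, and the gamma-delta T cell markers ranged from -0.25 without high IL-2 replicate 2 to 1.15 without low IL-2/IL-7 replicate 2. Of the genes that the naming rule took, none changed direction in these alternatives, and the calls of Ifng, Tcrg-C1, Cd68, Ikzf4, Itga2b and mt-Nd3 were lost in at least 1 of them, while that of Trdc was gained. Over all alternatives, 2458 of the values of these genes kept their call or lack of one, 21 lost it and 4 gained it. Simulated 1.5-fold changes were recovered in 40.0% of cases, under settings that differ from these data in the share of changed genes.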

Other observations

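The tests of the groups, genes and explanations in this part were chosen after the values had been seen, except that the prediction on genes apart in both libraries numbered 1 was written before its count was known. That test itself was chosen after the V gene pattern, and it replaced a first version on genes read in the libraries of 1 number alone, which found only Mmp16 for number 1 and 0 genes for numbers 2 and 3. Of 20 cytosolic tRNA synthetase genes, 17 were higher in high IL-2 and none in low IL-2/IL-7 (1 without high IL-2 replicate 1), led by Cars, Aars and Yars, which fell by 2.45, 1.93 and 1.79 on the log2 scale in low IL-2/IL-7 (adjusted p from 7.15e-07 to 2.25e-06). Of 37 proteasome subunit genes, 29 were higher in high IL-2 and 8 were not called, with a median of -0.50, and 18 were higher in high IL-2 without both libraries numbered 1; Psmb7 and Psmd12 fell by 1.17 and 1.10 in low IL-2/IL-7. Of 15 chaperones and folding enzymes of the endoplasmic reticulum, 13 were higher in high IL-2, including Sdf2l1, P4hb and Hspa5, which fell by 2.44, 1.70 and 1.54 in low IL-2/IL-7, and Dnajb9 was higher in low IL-2/IL-7 by 0.93.

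Cytosolic ribosomal protein genes went the other way: 39 of 81 were higher in low IL-2/IL-7, 2 (Rpl13a and Rpl41) were higher in high IL-2 and 40 were not called. Without both libraries numbered 1, 24 were higher in low IL-2/IL-7. The count toward high IL-2 was 0 without low IL-2/IL-7 replicate 2 or 3, 1 without high IL-2 replicate 3 and 5 without high IL-2 replicate 2. Their median log2 difference was 0.46, and it was 0.48 with TMM scaling, 0.51 with library totals and 0.57 with totals that leave these genes out. Rps14 and Rps7 were higher in low IL-2/IL-7 by 1.18 and 1.03. Many have processed pseudogenes that can take reads, and Rpl13a was higher in low IL-2/IL-7 in the FPKM values. Of 77 mitochondrial ribosomal protein genes, 29 were higher in high IL-2 and 5 in low IL-2/IL-7; 19 were higher in high IL-2 without low IL-2/IL-7 replicate 2 or 3, 9 were higher in low IL-2/IL-7 without high IL-2 replicate 2, and 3 were without both libraries numbered 1. The Kruppel-like factors split: Klf2, Klf3 and Klf13 were higher in low IL-2/IL-7 by 4.06, 3.31 and 1.15, and Klf6, Klf7 and Klf10 fell there by 0.91, 1.05 and 0.94; of all 13, 6 were higher in low IL-2/IL-7 and 3 without both libraries numbered 1. Spp1 (osteopontin) had 16.6 ± 13.5 normalized counts in low IL-2/IL-7 and 6901 in high IL-2 replicate 1, against 1526 and 1323 in the other high IL-2 libraries.

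The libraries numbered 1 of both groups shared 1 beta chain and 1 alpha chain V gene, although the labels describe all mice alike. Separate outgrowth of clones would have to bring up the same alpha chain and the same beta chain V gene in both cultures, and was not tested. A mixture with gamma-delta T cells in these cultures is not excluded. Dilution of the other T cells alone would lower all V genes alike and leave the shares as they were. Trav14-1 had 921 and 634 reads in these libraries and 35 to 59 in the other 4, and Trbv13-3 also had more reads. These values argue against such dilution as the cause of the V gene shares. Log2 ratios of number 1 over the others, in low IL-2/IL-7 and high IL-2, were 0.28 and -0.05 for Trbc1, -0.19 and -0.23 for Trbc2, and -0.55 and -0.48 for Trac. Tests of separate outgrowth and of a mixture by the shares of Trav14-1 and Trbv13-3 were dropped because these shares are the pattern itself. One cell source behind both libraries is a candidate explanation: 21 genes outside the receptor loci stood at least 2-fold apart in both libraries numbered 1 in the same direction and 7 in opposite directions, against 3 in the same and 0 in opposite directions for number 2 and 0 and 8 for number 3. A mouse line with a fixed Trav14 and Trbv13-3 receptor, such as the LCMV-specific P14 line, may be that source, which the files cannot settle. For the Trdc reads, gamma-delta T cells stay open, since Tcrg-C1, Tcrg-C2 and Tcrg-C4 had a median log2 ratio of 0.94 in the same libraries, below the 3.00 and 4.47 of Trdc, with Tcrg-C2 at -0.41 in high IL-2.

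Ighm had 13610 normalized counts in low IL-2/IL-7, where Cd79b, Ighd and Cd79a, also higher there, stood at 121, 110 and 28.2. B cells mixed in would bring light chain and surface antigen reads, but Igkc, Cd74 and Ms4a1 together came to 0.0981% of the Ighm reads. Transcription of the constant region without a V gene, in the T cells themselves, is a candidate explanation, in line with Ighv reads at no more than 0.150% of the Ighm reads in any low IL-2/IL-7 library. Why it differs between the cytokine conditions was not tested.

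H2-Ab1 stood at 988 normalized counts in high IL-2, where the other classical class II chains H2-Aa and H2-Eb1 stood at 7.28 and 6.89. Antigen-presenting cells mixed in would bring Cd74, H2-Aa and H2-Eb1, but the highest of these, Cd74, came to 2.38% of the H2-Ab1 reads. Reads shared with related class II genes were first tested over all of them, where H2-DMa came to 81.8% of the H2-Ab1 reads and left this undecided. The test was then narrowed, after that result, to relatives higher in high IL-2, since H2-DMa was lower there (808 against 1245 normalized counts), and the highest, H2-DMb2, came to 14.0%, which argues against shared reads as the whole cause. A regulation of H2-Ab1 in these T cells by the culture condition stays open and was not tested.

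Of the 10 splits of the 6 libraries into 3 and 3, only the real 1 reached its counts of 8459 changed genes, 4947 at least 2-fold genes and 20 lists, and 10 splits are too few for a share under 0.05. The highest of the other splits gave 0 genes at an adjusted p below 0.05 (limma), 0 at least 2-fold genes and 17 lists. At an unadjusted p below 0.05 they gave up to 675 genes. Each of these splits put libraries of both groups on the same side. The group difference then adds to the spread within a side, which by itself keeps gene calls low. The 0 genes therefore do not show how often the gene test makes false calls. The 17 lists came from camera with the preset correlation, with which each of the other splits called at least 11 lists.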
